A study of Homo sapiens with 6 samples.

How the data were processed

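The series holds 6 RNA samples of HCC-LM3, a human hepatocellular carcinoma line with a high tendency to metastasise when grafted into mice. Cells carried either a lentiviral shRNA against ASPP2, the protein encoded by TP53BP2, or a control shRNA without that target, and RNA was taken a week after infection, per the labels' protocols. Each group, called shASPP2 and shNon here, has 3 samples from separate cultures, per the labels. Each sample was hybridised to its own NimbleGen expression array in 1 colour (Cy3).

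The authors deposited 1 intensity per array feature and sample, on a linear scale, made with RMA per the submitters' processing notes. RMA as usually defined corrects background, equalises the distribution of probe intensities between arrays and summarises the probes of a feature. Its version and settings, the scanner software and any outlier handling are not given in the sources used here. Such a summary pulls dim features towards a common floor, so that fold changes of dim genes come out too small. It also hides any difference in total RNA per cell. Scan dates, slides, culture days and background images were not used here. The files listed 45033 features, of which 45031 were summarised from 3 probes each, and 1 further row of 2508 random-sequence probes that match no transcript. That row served as the level of unspecific signal and entered no test. The deposited value table held the same intensities as the per-sample files, with 0 differing cells.

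The array's design names features by accession, with positions on hg18, and coordinates are given on that build. Symbols were updated through gene identifiers in a RefSeq gene table of GRCh38.p14, which was used for names only. Gene identifiers named 38916 features and accessions 78. The file's own name was kept for 3954 features, and 2085 features stayed unnamed. The named features represent 23593 genes, of which 11859 have several features. The feature with the highest mean log2 intensity over the 6 arrays stood for a gene, and the other features of each named gene were compared with it.

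Log2 of the deposited intensities was fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with group as the only term. P-values are two-sided, and Benjamini-Hochberg adjustment was over all 45033 features or all 23593 genes, with a threshold of 0.05. Fold changes are shASPP2 minus shNon on the log2 scale, so positive values are higher after knockdown. Errors of intensities are SDs over 3 arrays, and errors of log2 fold changes are limma's moderated standard errors (SE). With 3 arrays per group the number of arrays limits the precision, and an exact permutation test of a single value cannot go below p = 0.1.

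Before the data were examined, 38 gene lists were fixed for this line and this treatment. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 38 lists. Camera with a correlation estimated from these arrays and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were alternatives. Members of a list were also counted past an adjusted p of 0.05 over all genes and adjusted over the list alone. The adjustment over a list alone does not account for the number of lists. The rule for named genes was fixed at the same time. It takes the 3 ASPP genes. It takes up to 12 genes in each direction with the largest fold change among those past the threshold, with no overlap between the groups' arrays and a higher group mean above the median of all genes, leaving out locus and clone names. It takes the 4 members with the smallest p of each list that camera called or that held at least 3 members past the threshold over all genes. It also takes the 2 members with the smallest p of the epithelial, mesenchymal, Wnt, p53, autophagy, hepatocyte and interferon lists. Other genes are said to be outside the rule where they appear.

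The fit was tested on simulated data for this comparison over 23593 genes. Each gene's spread was drawn at random from the distribution that limma fitted to the real arrays. It was the same in both groups and did not depend on the gene's level, unlike the real arrays, where shNon was more variable. The shares below hold for that setting only. It called 0.2% of genes changed 1.5-fold, 3.8% of those changed 2-fold, 68.4% of those changed 4-fold and 90.2% of those changed 8-fold, against 0.02% of unchanged genes. Camera called a list of 25 genes shifted by 0.5 log2 in 100% of simulations. Genes were drawn independently there and shifted by the same amount, so this share does not cover lists whose genes vary together. Single genes changed 2-fold or less were thus mostly missed by this fit in the simulations, and the alternatives were not simulated.

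The alternatives tried were the deposited value table, median centring, cyclic loess, 2 filters on dim features, trend with robust variance, array weights, the replicate number as a block, the mean of a gene's features, a test of the gene count against a fold of 1.2 (limma's treat), and each array left out. Counts of list members without each array, and the ASPP and p53 family list without TP53BP2, were added after the data had been seen. Fits without an array have fewer samples, so fewer calls tend to follow whichever array is left out. Tables were written and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.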

Results

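The effect of ASPP2 knockdown on the transcriptome of HCC-LM3 hepatocellular carcinoma cells was measured on 6 1-colour arrays, 3 of control-infected cells (shNon) and 3 of cells infected with the ASPP2 shRNA (shASPP2). ASPP2 binds p53 and stimulates its action on apoptosis genes, and it is also a partner of cell polarity proteins at junctions. Median feature intensity was between 111 and 122 on the 6 arrays, and between 58.9% and 60.9% of features lay above 2 times the random-probe level. That level was 32.6 ± 0.752 in shNon and 30.6 ± 0.170 in shASPP2 (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest possible). Arrays correlated across features at r = 0.983 to 0.984 within shASPP2, 0.958 to 0.972 within shNon and 0.960 to 0.979 between the groups. The shNon arrays were the more variable group, with a median SD of 0.31 log2 against 0.23 in shASPP2, and shNon array 3 had the lowest correlations with the rest.

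The target was read first. TP53BP2, which encodes ASPP2 (chromosome 1, 222034412 to 222100255, hg18), had an intensity of 424 ± 81.9 in shNon and 197 ± 43.5 in shASPP2 (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest possible). Its log2 fold change was -1.11 (SE 0.249, 95% interval -1.70 to -0.53), so that 46.2% of the control signal was left. All 3 shASPP2 arrays lay below all 3 shNon arrays, which goes with the labels. The limma adjusted p over all genes was 0.204, so the target itself was not past the threshold. With trend and robust variance it was (adjusted p = 0.0256; adjusted p between 0.0256 and 0.585 over the alternatives run for single genes). The second TP53BP2 feature had a log2 fold change of -1.41. The other ASPP genes did not differ beyond the spread between arrays, with log2 fold changes of -0.29 (SE 0.208, adjusted p = 0.633) for PPP1R13B (ASPP1) and -0.38 (SE 0.403, adjusted p = 0.755) for PPP1R13L (iASPP).

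Few single genes passed the test. Of 23593 genes, 24 were past an adjusted p of 0.05 in limma, 10 higher and 14 lower in shASPP2, all by at least 2-fold. After median centring of each array the split was 9 higher and 20 lower. At feature level 62 of 45033 features passed, 24 higher and 38 lower. At an unadjusted p under 0.05 there were 2705 genes, where 1180 are expected by chance, and 18.8% of genes had groups that did not overlap, where chance gives 10%. In all 24 genes the groups' arrays did not overlap, so leaving out an array could not change the sign. Their log2 fold changes then moved by at most 0.23.

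Among the genes that rose, SOCS2, a feedback inhibitor of growth hormone and cytokine signalling, had the largest change. It went from an intensity of 200 ± 24.7 to 1054 ± 116 (log2 fold change 2.40, SE 0.185, adjusted p = 0.0168). GLIPR1, a gene first described in glioma, rose from 735 ± 26.4 to 3447 ± 445 (2.22, SE 0.173, adjusted p = 0.0168). HMOX1, the inducible haem oxygenase, rose from 1383 ± 125 to 5504 ± 552 (1.99, SE 0.174, adjusted p = 0.0230). WNT7B, a secreted Wnt ligand, rose by 2.09, and LYVE1, a hyaluronan receptor of lymphatic and liver sinusoidal endothelium, by 2.01 log2. The basement membrane collagen COL4A2 rose by 1.90, INSIG1, which holds back sterol-regulated transcription, by 1.75, and NPR3, the natriuretic peptide clearance receptor, by 1.68 log2, with adjusted p-values of 0.0280, 0.0296, 0.0310, 0.0296 and 0.0310 in limma for these 5 genes in that order. COL4A2 and LYVE1 were dim in shNon, at 38.3 ± 4.95 and 50.9 ± 7.38, close to the random-probe level, so the sizes of their rises are uncertain. WNT7B was also low in shNon, at 65.9 ± 11.1, which limits the size of its rise in the same way. LYVE1 was not past the threshold with cyclic loess (1.94 log2, adjusted p = 0.0506). Outside the naming rule, C5orf23 and LOC645858 also rose, by 1.96 and 1.68 log2, and the latter was dim in shNon at 47.3 ± 7.32, so the size of its rise is uncertain.

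The largest changes were falls. The class I alcohol dehydrogenases ADH1C and ADH1A had log2 fold changes of -3.33 (SE 0.190, adjusted p = 0.00971) and -3.26 (SE 0.213, adjusted p = 0.0125). ADH1C went from 5684 ± 924 to 563 ± 50.2 and ADH1A from 4978 ± 373 to 528 ± 126. Both lie close together on chromosome 4, at 100476900 to 100492883 and 100416546 to 100431165 (hg18), with ADH1B between them. The sequences of ADH1A, ADH1B and ADH1C are so alike that the array may not separate them. CYP26B1, which breaks down retinoic acid, fell by 3.17 (SE 0.264, adjusted p = 0.0219), and NOX1, a superoxide-producing NADPH oxidase, by 3.01 log2 (SE 0.260, adjusted p = 0.0230). The second CYP26B1 feature had -1.93, and at feature level its adjusted p was 0.146. Of the 4 NOX1 features, 3 had log2 fold changes from -3.01 to -2.82, and the other, dim in both groups at 39.7 ± 12.8 and 23.8 ± 1.75, had -0.69. In shASPP2 the NOX1 feature used was at 59.7 ± 14.9, under 2 times the random-probe level, so the size of its fall is uncertain. PTGS1, the constitutive cyclooxygenase, fell by 2.16, LCN2, an iron-siderophore carrier, by 1.60, and IGFBP3, a carrier of insulin-like growth factors, by 1.55 log2, with adjusted p-values of 0.0296, 0.0296 and 0.0379. Outside the rule, FMO5 was 2.83-fold and GSDMB 2.72-fold lower.

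**Figure D1:**
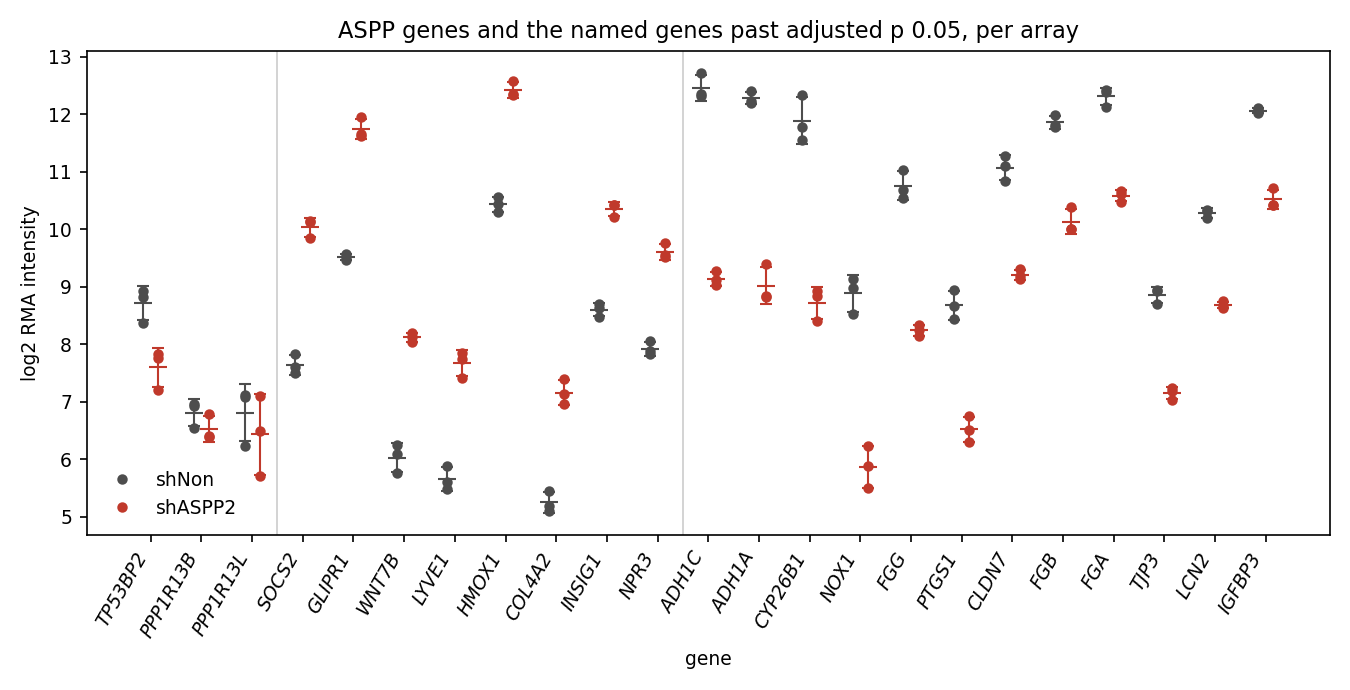
Log2 RMA intensity (y axis) of the ASPP genes and the named genes past an adjusted p of 0.05 (x axis), with a point per array, the group mean as a horizontal tick and 1 SD as the bar (n = 3 per group). For TP53BP2 and each gene to the right of PPP1R13L, the 3 shASPP2 arrays all lie on the same side of the 3 shNon arrays.

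The counts of genes past the threshold fell when any array was left out. Each such fit has fewer samples, which by itself makes calls harder, so the lower counts do not show dependence on single arrays. The log2 fold changes of the 24 genes stayed at 1.41 or more in size. Without shNon array 1, 2 or 3 limma called 5, 0 and 6 genes, and without any of the 3 shASPP2 arrays 0 genes, although 1686 to 3106 genes then had an unadjusted p under 0.05. With trend and robust variance 506 genes passed, and after removing features below the median level 247 did. Tested against a fold of 1.2, 16 genes passed. Among the named genes other than TP53BP2, trend and robust variance added 19 calls and lost none. The replicate block, which estimates more terms from the same arrays, lost all 20.

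Fibrinogen transcripts stood out among the hepatocyte genes. All 3 chains fell, FGG by 2.51 (SE 0.193, adjusted p = 0.0168), FGB by 1.73 (SE 0.186, adjusted p = 0.0361) and FGA by 1.73 log2 (SE 0.172, adjusted p = 0.0296). FGA went from 5094 ± 528 to 1535 ± 103. The 3 genes form a cluster on chromosome 4 between 155703612 and 155753352 (hg18). Of the 35 hepatocyte genes these were the only 3 past the threshold over all genes. Adjusted over the list alone, 5 fell and 1 rose, with the pioneer factor FOXA1 at -0.91 among those that fell (limma adjusted p = 0.0175 for FOXA1 over the list). This count of 6 was 3 without shASPP2 array 2. The hepatocyte list as a whole had a median of -0.03 log2 and was not called by camera (adjusted p = 0.330). Fry, which does not set the list against other genes, gave an adjusted p of 0.0377.

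Genes of cholesterol synthesis and uptake were higher in shASPP2 as a group. Of 24 measured members, 18 rose when adjusted over the list alone, none fell and 6 did not pass, while 1, INSIG1, passed over all genes. The list's median log2 fold change was 0.85 and camera gave an adjusted p of 8.32e-15. With an estimated correlation the call was lost (adjusted p = 0.126 with an estimated correlation). MVD, mevalonate diphosphate decarboxylase, rose from 236 ± 38.7 to 663 ± 101 (log2 fold change 1.49, SE 0.208, limma adjusted p = 0.00206 over the list). SQLE, squalene epoxidase, rose from 1718 ± 152 to 3603 ± 52.2 (1.07, SE 0.163, limma adjusted p = 0.00233 over the list), and MSMO1, a sterol methyl oxidase, by 1.21 log2 (SE 0.205). The count of members was between 13 and 17 when single arrays were left out.

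Heat shock genes were also higher. Of 19 measured members, 8 rose adjusted over the list alone and none passed over all genes, with a median of 0.48 log2 and a camera adjusted p of 3.85e-09 (adjusted p = 0.0874 with an estimated correlation, so that the call was lost). CRYAB, a small heat shock protein, had a log2 fold change of 1.29 (SE 0.222), HSPB8 0.92 (SE 0.173), HSPH1, an HSP70 exchange factor, 0.91 (SE 0.179) and the co-chaperone BAG3 0.70 (SE 0.180), and these 4 passed adjusted over the list alone. CRYAB was dim, at 45.5 ± 7.24 in shNon. The count of 8 members fell to 3 without shNon array 1 or 2 or shASPP2 array 2 or 3, and to 4 without shNon array 3 or shASPP2 array 1. The unfolded protein response list had a median of 0.11 log2 and was not called (adjusted p = 0.556).

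**Figure D2:**
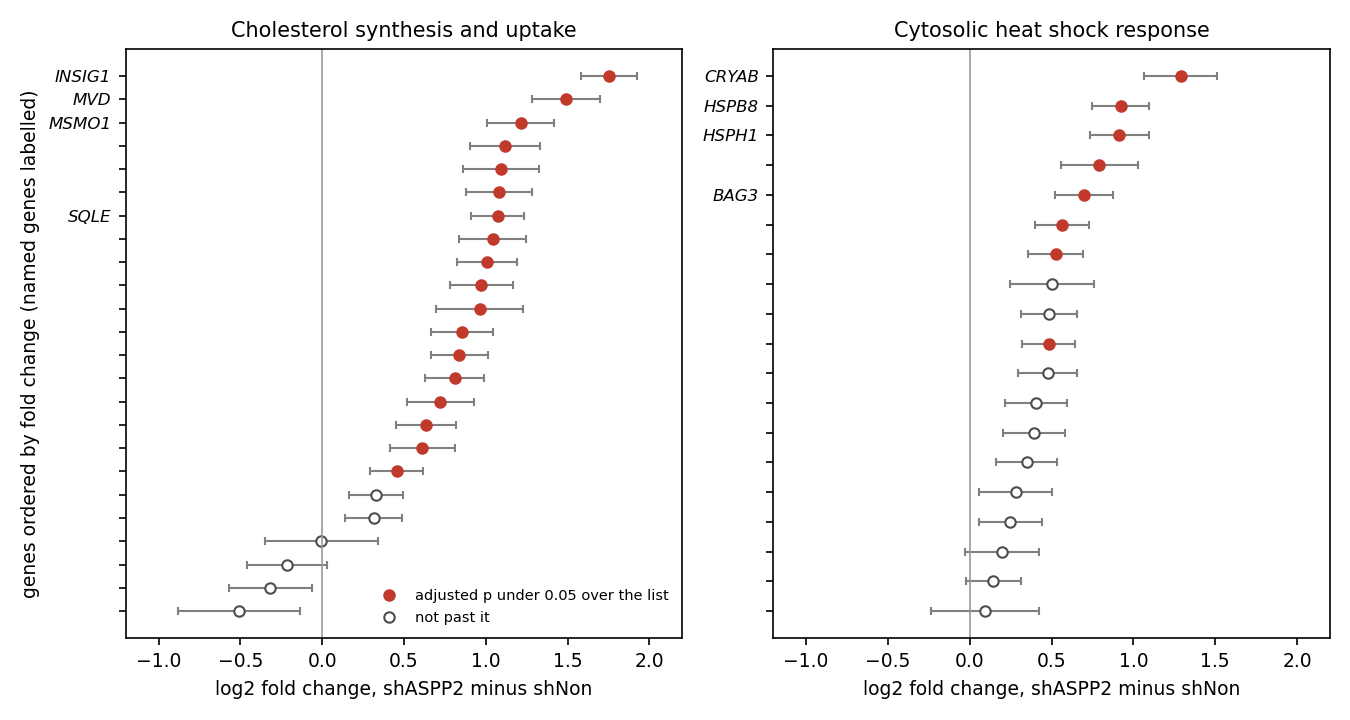
Log2 fold change, shASPP2 minus shNon (x axis), of each measured gene (y axis, ordered by fold change, with the genes named in the text labelled) of the cholesterol list (left, 24 genes) and the heat shock list (right, 19 genes), with bars of 1 SE. Filled points passed an adjusted p of 0.05 over the list alone, 18 in the left panel and 8 in the right, and all of these lie to the right of 0.

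A further 4 lists passed camera, all towards higher levels, and all lost the call with an estimated correlation. For TGF-beta targets (22 genes) the median was 0.41 log2, with a camera adjusted p of 8.01e-04 and an adjusted p = 0.142 with an estimated correlation. COL4A2 passed over all genes, and it rose together with JUNB (1.13), ID3 (0.98) and ID2 (0.69) when adjusted over the list alone. ID2 and ID3 are also direct targets of BMP signalling. This count of 4 members was 2 without shASPP2 array 2 or 3. For histone genes (14 genes) the median was 0.55 log2, with a camera adjusted p of 0.00275 (adjusted p = 0.142 with an estimated correlation). Adjusted over the list alone, 5 histone genes rose and 1 fell. The named ones were H1-2 (1.14), H2BC12 (1.09), H2BC5 (0.91) and H2BC4 (0.73), and histone genes of 1 type are near-identical, so single members are uncertain. The count of 6 was 3 without shNon array 3, 4 without shASPP2 array 3 and 0 without shASPP2 array 1 or 2.

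Ribosome biogenesis genes (27 genes) had a median of only 0.14 log2 and no member past the threshold, with a camera adjusted p of 0.00473 (adjusted p = 0.142 with an estimated correlation). The list's median lay at percentile 97.78 of 10000 lists of the same size matched on mean log2 intensity. A bias that depends on brightness therefore stays open for this list. The smallest p-values belonged to RRP9 (log2 fold change 0.52), RRP12 (0.48), NOP2 (0.44) and BOP1 (0.75). For immediate early genes (27 genes) the median was 0.31 log2 and the camera adjusted p 0.0305 (adjusted p = 0.531 with an estimated correlation). Its members went both ways. Adjusted over the list alone, 4 rose, among them JUNB and the phosphatase gene DUSP1 (0.98), and 2 fell, NR4A2 (-1.12) and EGR1 (-1.12). The falls were smaller on their other features, at -0.51 and -0.30 for NR4A2 and -0.37 for EGR1. The list was not called without shNon array 1 or 3 or shASPP2 array 2 or 3, with adjusted p-values up to 0.194. Its count of 6 members was 3 without shNon array 1, 4 without shNon array 2, 1 without shASPP2 array 1 and 0 without shASPP2 array 2 or 3.

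**Figure D3:**
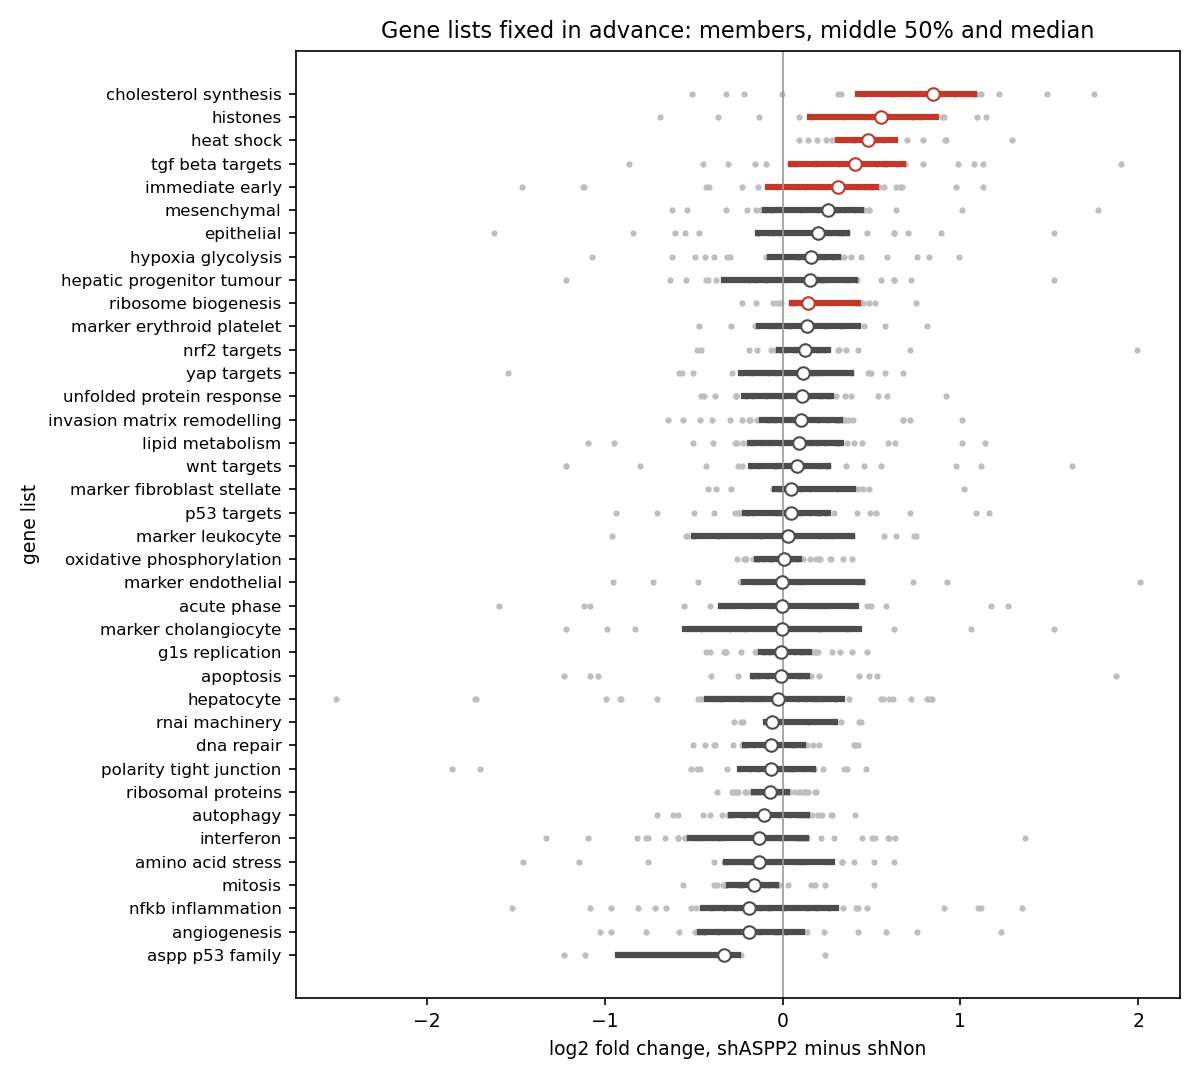
Log2 fold change, shASPP2 minus shNon (x axis), of the members of the 38 gene lists (y axis), with a grey point per gene, a bar over the middle 50% of members and an open circle at the median. Red marks the 6 lists with a camera adjusted p under 0.05 at the preset correlation, with medians from 0.14 to 0.85.

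Junction genes were examined because ASPP2 acts with polarity proteins. Of 25 polarity and tight junction genes, 2 fell and passed over all genes, CLDN7, a claudin of epithelial junctions (-1.86, SE 0.184, adjusted p = 0.0296), and TJP3, the scaffold ZO-3 (-1.70, SE 0.170, adjusted p = 0.0296). The other 23 did not pass, the list's median was -0.07 log2, and camera did not call it (adjusted p = 0.273), while fry gave an adjusted p of 0.0189. CDH1, encoding E-cadherin, went from 613 ± 72.7 to 200 ± 32.9 (log2 fold change -1.62, SE 0.199). Its adjusted p over all genes was 0.0518, over the threshold, while its feature at feature level had 0.0486. It passed under 7 alternatives, and its adjusted p was between 3.70e-04 (trend and robust variance) and 0.458 (replicate block) over the alternatives run for single genes. Adjusted over the list alone, CDH1 was the only 1 of 25 epithelial genes to pass, and 2 passed without shASPP2 array 3. The keratin gene KRT8 had a log2 fold change of 0.71 and passed with trend and robust variance (adjusted p = 0.00207), and the epithelial list's median was 0.20 (camera adjusted p = 0.367). Of 25 mesenchymal genes none passed, with a median of 0.25 log2 (camera adjusted p = 0.205, 0.0370 without shNon array 1, and 0.531 with an estimated correlation). SNAI2, which encodes a repressor of E-cadherin, had a log2 fold change of 1.78 (SE 0.387, adjusted p = 0.201), and passed with trend and robust variance (adjusted p = 0.00831). SPARC had 0.64, but its other feature pointed the opposite way at -0.48. Both SPARC features lay near the random-probe level, at 32.5 ± 5.04 and 38.6 ± 4.76 in shNon, so neither value is a reliable measure.

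Wnt target genes did not move together. Of 25, 2 rose and 2 fell adjusted over the list alone, with TCF7 at 0.97 (SE 0.163) and SOX9 at -1.22 (SE 0.233; -1.14 and -0.63 on its other features), and the camera adjusted p was 0.556. That count of 4 was 6 without shNon array 3, 2 without shNon array 1 or shASPP2 array 3, and 0 without shASPP2 array 1 or 2. SOX9 was dim in shASPP2, at 42.8 ± 10.5, so the size of its fall is uncertain. Of 28 p53 target genes none passed, adjusted over the list alone or over all genes, with a median of 0.05 log2 and a camera adjusted p of 0.774. CDKN1A, the p21 inhibitor of cell cycle kinases, went from 563 ± 219 to 1198 ± 159 (log2 fold change 1.16, SE 0.304, adjusted p = 0.254), and passed with trend and robust variance (adjusted p = 0.0190). PHLDA3 had -0.94 on the feature used and 0.54 on the other. The feature used was dim in shASPP2, at 53.5 ± 7.59, and the other in shNon, at 59.0 ± 18.4. Of 30 autophagy genes none passed (median -0.11 log2, camera adjusted p = 0.275, fry adjusted p = 0.0163), with DRAM1 at -0.59 and GABARAPL1 at -0.61. Of 39 interferon genes none passed (median -0.13 log2, camera adjusted p = 0.284), with IFIH1 at -1.10 and SAMD9 at 0.52. Apoptosis genes had a median of -0.01 log2 (adjusted p = 0.947), G1/S replication genes of -0.01 (adjusted p = 0.917) and mitosis genes of -0.16 (adjusted p = 0.0541). The mitosis list was called in 8 of 15 other settings, among them without shNon array 2 (adjusted p = 0.0409) or shASPP2 array 1 (adjusted p = 0.0292), but not with an estimated correlation (adjusted p = 0.531).

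Markers of cells that a tumour line should not hold gave no list called by camera. This compares the groups and does not show whether such markers were absent. Over 2 times the random-probe level were 5 of 14 fibroblast and stellate, 4 of 14 endothelial and 4 of 17 leukocyte markers. So were 6 of 12 cholangiocyte and 1 of 10 erythroid and platelet markers. The camera adjusted p was 0.575 for fibroblast and stellate cells, 0.587 for endothelium, 0.928 for leukocytes, 0.648 for cholangiocytes and 0.648 for the erythroid and platelet lineage, which fell to 0.0176 without shASPP2 array 3 (0.882 with an estimated correlation). Fry gave an adjusted p of 0.0163 for endothelium. In the endothelial list, whose median was near 0 and whose mean was 0.14 log2, LYVE1 rose, ESAM (0.93) rose and PECAM1 (-0.96) fell adjusted over the list alone, and the last 2 are outside the naming rule.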

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

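No named gene changed direction under any alternative run, and the value table gave the same intensities. For named genes whose groups did not overlap, leaving out an array could not change the direction. The number of genes past the threshold was sensitive. Against 24 genes and 62 features, limma called 506 genes and 952 features with trend and robust variance. Once features below the median level were removed, it called 247 genes and 405 features. That filter leaves fewer genes to test, but it also changes the spread that limma shares over genes. The unadjusted limma p of TP53BP2 went from 0.0028 to 0.0015 at the same fold change. The mean of a gene's features gave 40 genes. All 24 genes were among those called with trend and robust variance. The cause was not tested for the filter, the variance model or the mean of features. TP53BP2 passed only with trend and robust variance, at the same log2 fold change of -1.11. Leaving out single arrays gave 0 to 17 features, 0 to 6 genes, 6 to 7 lists and a TP53BP2 log2 fold change of -1.28 to -0.92, with fewer samples in each fit. The replicate block gave 0 features, 0 genes and 7 lists, with 2208 genes at an unadjusted p under 0.05. The numbers do not mark shared cultures in the labels, and deviations of same-numbered arrays correlated at 0.056, -0.076 and -0.126, so not every array correlated best with its own number. Camera called 0 lists with an estimated correlation, where the lowest adjusted p was 0.0874, and fry called 10, adding the NRF2, polarity, autophagy, hepatocyte and endothelial lists and dropping immediate early genes. The cholesterol, heat shock, TGF-beta, histone and ribosome biogenesis lists were called in 15 of 15 other settings, immediate early genes in 11 of 15, mitosis in 8 of 15 and the ASPP and p53 family in 9 of 14. These settings include the value table, whose result was fixed by its identical intensities, and leave out fry and the estimated correlation. Mean log2 fold changes near 0 of uncalled lists changed sign. With median centring they were -0.0327 for YAP targets, -0.0309 for oxidative phosphorylation and -0.0140 for leukocyte markers. With cyclic loess they were -0.0173 for YAP targets and -0.0116 for oxidative phosphorylation. Removing the dimmest 25% of features gave -0.0072 for YAP targets, -0.0092 for leukocyte and 5e-04 for cholangiocyte markers, and removing features below the median gave 0.0663 for apoptosis. Array weights gave -0.0112 for YAP targets and -0.0217 for leukocyte markers. The mean of features gave 0.0183 for apoptosis, 0.0183 for G1/S replication and 0.0157 for cholangiocyte markers. Without single arrays the means ran from -0.0635 to 0.1149 for YAP targets, -0.0282 to 0.0126 for G1/S replication, -0.1164 to 0.0341 for DNA repair, -0.0298 to 0.0206 for oxidative phosphorylation, -0.0311 to 0.1031 for leukocyte, -0.0901 to 0.0769 for cholangiocyte and -0.0021 to 0.4053 for erythroid and platelet markers. The cause was not tested. Background correction, another probe summary and a slide or scan block were not run, since the values were already summarised and no slide is given in the sources used here. Signal over background limits dim genes, since 58.9% to 60.9% of features per array lay above 2 times the random-probe level.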

Other observations

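The patterns and the 2 additional gene lists tested here were chosen after the fold changes of single genes had been seen, and each test's outcome bounds were set before that test was run.

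Several lists fixed in advance held members that changed in opposite directions. Of the genes named in this paragraph, only LCN2 passed over all genes. The others passed only when adjusted over their own list, with no adjustment across lists. The genes named in this paragraph other than LCN2 are outside the naming rule and were picked after their values were seen. Of 31 NF-kB and inflammation genes, 5 fell and 3 rose adjusted over the list alone in limma. The inducible cyclooxygenase gene PTGS2 fell by 1.52, the apoptosis inhibitor gene BIRC3 by 1.08, the adhesion receptor gene ICAM1 by 0.81 and IL1B by 0.96 log2. The growth factor gene CSF1 rose by 1.35, IL1A by 1.10 and IL6 by 0.91 log2. Camera did not call this list (adjusted p = 0.221), except where features below the median level were removed (0.00624). With an estimated correlation its adjusted p was 0.531. Its count of 8 members was 4 without shNon array 2, 2 without shASPP2 array 1 or 3 and 1 without shASPP2 array 2. Of 20 acute phase genes, 4 fell and 3 rose, with LCN2 at -1.60, FGL1 at -1.12 and CFB at -1.09 on one side and HAMP, which encodes hepcidin, at 1.17 and SOCS3 at 1.26 on the other (camera adjusted p = 0.655). That count of 7 was 3 without shNon array 2, 4 without shASPP2 array 2 and 1 without shASPP2 array 1 or 3.

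Of 20 measured amino acid stress genes, 3 fell adjusted over the list alone, ASNS, asparagine synthetase, by 1.15, CBS, cystathionine beta-synthase, by 1.46, and the serine synthesis gene PSAT1 by 0.76 log2, and STC2 rose by 0.62 log2 (camera adjusted p = 0.367). The count of 4 was 2 without shNon array 1 or 2 or shASPP2 array 2 or 3. Of 28 other lipid genes, the fatty acid transporter gene CD36 rose by 1.14 and the desaturase gene FADS2 by 1.01, while the nuclear receptor gene PPARA fell by 1.10 log2 (camera adjusted p = 0.330). That count of 3 was 1 without shNon array 1 or shASPP2 array 2 and 0 without shASPP2 array 1. Among YAP targets IGFBP3 alone passed. BMF, a pro-apoptotic BH3-only gene, rose by 1.87 log2, 1 of 2 apoptosis genes past the threshold adjusted over the list alone. That count of 2 was 1 without each of the 3 shASPP2 arrays. All these genes are outside the naming rule except IGFBP3, and of them only IGFBP3 passed over all genes.

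With every array and the preset correlation, camera did not call the remaining lists. Adjusted p-values were 0.0534 for the ASPP and p53 family, which was called in 9 of 14 other settings but not with an estimated correlation (adjusted p = 0.531), and 0.154 for NRF2 targets, where HMOX1 was the only member past the threshold. The family list holds TP53BP2, the target itself, so its fall in part restates the knockdown. Without TP53BP2, a test added after the data were seen, its 5 other genes had a camera adjusted p of 0.255. The NRF2 list was called with trend and robust variance (adjusted p = 0.0391) and by fry (adjusted p = 0.0121), but not with an estimated correlation (adjusted p = 0.531). For the others camera gave adjusted p-values of 0.275 for angiogenesis, 0.275 for ribosomal proteins, 0.275 for hypoxia and glycolysis, 0.330 for invasion and matrix remodelling, 0.556 for DNA repair, 0.648 for YAP targets, 0.901 for the RNA interference machinery, 0.985 for hepatic progenitor genes and 0.985 for oxidative phosphorylation. Camera's direction and the median differed in sign for endothelial markers, for the RNA interference list (median -0.06, mean 0.05) and for oxidative phosphorylation (median 0.01).

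NPR3 and C5orf23, both past the threshold and higher by 1.68 and 1.96 log2, are neighbours on chromosome 5, at 32747296 to 32822300 and 32824701 to 32827576 (hg18). Whether the second feature reads a longer NPR3 transcript was not tested.

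Levels of genes typical of liver and of gut epithelium were compared with the random-probe level, each on its own feature. In shNon, the albumin gene ALB had an intensity of 86.5 ± 5.74, or 2.66 times that level, AFP 43.6 ± 16.2, TTR 34.9 ± 4.30 and SERPINA1 26.0 ± 2.75, while HNF4A, a transcription factor of liver and gut, had 2562 ± 386. The liver genes FGA and FGB were bright, at 5094 ± 528 and 3727 ± 293. The gut-type genes LGALS4, CEACAM6, CDH17 and AGR2 had 18078 ± 1280, 18684 ± 1243, 10291 ± 1067 and 17948 ± 2469, VIL1 2508 ± 405 and CDX2 407 ± 154. Other gut or epithelial genes lay near the random-probe level, with CDX1 at 46.2 ± 18.6, FABP1 at 1.26 times that level, FABP2 at 51.2 ± 41.1, MUC2 at 44.7 ± 7.16, TFF2 at 28.6 ± 7.72, KRT19 at 54.3 ± 22.1 and EPCAM at 29.3 ± 4.91. So both sets held bright and dim genes, low ALB, AFP, TTR and SERPINA1 are unusual for a hepatocellular line, and the identity of the line was not tested here. All these genes were chosen after their values were seen, and features differ in how strongly they bind, so their levels are not ranked.

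The rise of the cholesterol and heat shock lists was weighed against technical explanations. A bias that depends on brightness was argued against, since both lists' medians lay at percentile 100 of 10000 lists of the same size matched on mean log2 intensity. Dependence on shNon array 3, the array least like the rest, was argued against too at the preset correlation, since without it the higher of the camera adjusted p-values was 7.60e-07. With an estimated correlation neither list was called even with all arrays, so this holds for the preset correlation only. A difference in culture or harvest that runs with the group stays open and cannot be told apart from the knockdown, since 0 labels give a culture or harvest day. With 1 ASPP2 shRNA, an effect of that construct on other transcripts was not tested, and no test singled out a biological explanation.

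The falls of the fibrinogen and alcohol dehydrogenase genes share chromosome 4. Loss of most of the 5 Mb on either side of them was argued against. The 48 other genes there and over 2 times the random-probe level had a median of 0.0473 log2 (bootstrap 95% interval over genes -0.06 to 0.12). Such a median cannot show a loss limited to either gene cluster, which stays open. A general fall of hepatocyte genes by as much as the fibrinogen genes was argued against as well. The 15 other hepatocyte genes over 2 times the random-probe level had a median of -0.12 log2 (interval over genes -0.34 to 0.56), 7 higher and 8 lower. A smaller general fall lies within that interval and stays open. Within the alcohol dehydrogenase family ADH6 had -1.80 (adjusted p = 0.0820), ADH1B -2.15 (adjusted p = 0.361) and ADH5 -0.72 log2. Transcripts shared between ADH1A, ADH1B and ADH1C stay open as a reason for their like values, and no biological explanation was tested for the fibrinogen genes.

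Since CYP26B1 is induced by retinoic acid and alcohol dehydrogenases oxidise retinol, a lower expression of retinoic acid target genes was put as a hypothesis. A list of 24 such genes without CYP26B1 gave camera p = 0.0132 towards lower levels (adjusted over the 2 additional lists 0.0132; p = 0.146 with an estimated correlation), with 15 lower and 9 higher, where 17 of the 24 were over 2 times the random-probe level (median -0.39 log2). Its median of -0.28 log2 had a bootstrap 95% interval over genes of -0.49 to 0.17, and ICAM1 and TNFAIP2 are also in the NF-kB list, so the result may rest on a part of the list.

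Gut-type epithelial genes were the other such hypothesis, after TMPRSS2, MUC13 and 4 further genes had been seen to be lower. Without those 6, 22 of 27 genes were lower, with a median of -0.32 log2 (bootstrap 95% interval over genes -0.46 to -0.16) and camera p = 6.52e-04 (adjusted over the 2 additional lists 0.00130; p = 0.0569 with an estimated correlation). Only 15 of the 27 were over 2 times the random-probe level, with the same median of -0.32 log2, so the count of 22 includes genes near the floor. TFF1 had -1.06, CEACAM5 -0.78 and VIL1 -0.53, while CDX2, a master regulator of gut identity, had -0.07 log2, and no gene of the 27 was past the threshold over all genes. No technical explanation was tested for this pattern.

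Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many features, genes or lists past the threshold. The real split gave 62 features, 24 genes and 6 lists, and the highest of the others 14, 5 and 3. With 10 splits the share cannot fall under 0.05.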
